A study of Mucor circinelloides with 6 samples.

How the data were processed

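Per the labels, total RNA was extracted with the miRVana kit from 6 strains of Mucor circinelloides, and the short RNAs were sequenced on an Illumina (Solexa) instrument. Each of the 6 genotypes had 1 library. Groups were taken from the genotype label of each sample. Short RNA reads and counts were not analysed here, so no test between genotypes was made and no depth, interval or floor of a library is given. Nothing in the processed data gives a per-sample value (0 columns).

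The authors deposited a sequence file in FASTA format that holds 23 genomic scaffolds in A, C, G, T and N. Its header lines carry only scaffold numbers. The sequencing method, assembler, version and annotation behind it are not given in the sources used here, and no gene annotation or other reference genome was used. The numbers of the scaffolds are those of the file, and some numbers are skipped. Coordinates are scaffold positions counted from 1, both ends included. No exon, intron or gene name of any locus therefore comes from an annotation, and an open segment is a run of codons between stop codons, not a gene model. All counts are exact counts over this sequence and carry no sampling error; they depend on how well repeats were assembled, since collapsed copies lower the repeated share. Spread is given as the SD over the 14 scaffolds of at least 100000 bases, which are parts of 1 genome and not biological replicates.

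Open segments were runs of at least 100 codons without a stop codon or N in any of 6 frames. They were searched for the RNase III signature [DEQ][KRQT][LM]E[FYW][LV]GD[SARH], the polymerase motif D[LYFIMV]DGD followed by 5 residues, W and [DENQ], and the Argonaute motif G, any residue, DV[TSNQ]HP. A locus was an open segment with at least 1 match. The background was the number of loci with 100 random orders of the same pattern elements, the reversed order included. Segments of a family were aligned locally with BLOSUM62 (gap opening 11, extension 1), and each score was set beside 100 alignments to shuffled sequence. A pair of RNase III signatures had to lie on 1 strand within 3000 bases. For the search over a possible GT-AG intron of 40 to 150 bases, the start of the partial match and its GT were kept, and the sequence downstream was replaced by sequence from 1000 random places.

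Windows of 18 to 25 nt without N were counted over both strands, and a window was unique if it occurred once. This treats a read as matching only without mismatches. A base was called repeated if a 32-mer covering it occurred at least 2 times over both strands. GC content and dinucleotides were compared between repeated and single-copy bases within each large scaffold, with a two-sided permutation test of the mean difference (100000 random sign flips over scaffolds). The smallest permutation p-values reported carry the random error of the flips and are not ranked against each other. Adjusted p-values are Benjamini-Hochberg values over 4 comparisons: GC, TpA over ApT, the ratio of CpA and TpG to ApC and GpT, and 21-nt uniqueness inside against outside open segments. Inverted repeats had perfect arms of at least 24 bases and at most 500 bases between them, with direct repeats as background, and overlapping repeats were merged into 1 locus. tRNA-like loci were an A box TRGCNNARYNG and a B box GGTTCRANYCC, with both boxes read backwards as background. The searches were tested on a simulated sequence of 2000000 bases. In it, 40 of 40 planted RNase III signatures, 20 of 20 polymerase and 20 of 20 Argonaute motifs were found. So were 20 of 20 inverted repeats and 20 of 20 box pairs. All were planted as exact matches, the motifs without introns and the repeats with perfect arms. This checks the code, not how many real genes are found. The sign-flip test called 5.6% of 500 simulated cases of independent values without a difference. Copies of the same repeat can lie on several scaffolds. Real scaffolds are then not independent units, and their p-values may be too small.

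Motifs, thresholds, most tests and most alternatives were fixed before the data were examined. The rule for what the text names was also fixed then: the 10 longest scaffolds, every motif locus of a family with at most 10 loci, and the 5 inverted repeats with the longest arms. The other scaffolds named were singled out after their values were seen. The second polymerase motif, the split by open segments, the ribosomal RNA sites, the alignments, the signature search over an intron, the settings for low-complexity sequence, distinct windows and arms of at least 100 bases, and the results without scaffold 14 were added afterwards. Tests of the ratio of CpA and TpG to ApC and GpT, and of uniqueness inside against outside open segments, were not planned either. Shorter core motifs and other telomere units were also looked at before the second polymerase motif was chosen. After the values were seen, shares under an alternative setting came to be compared through a Wilson interval in place of the SD over scaffolds, which scaffold 14 inflates. Overlapping windows and neighbouring bases are not independent draws, so this interval is only a narrow yardstick, not a sampling error, and it marks almost any other setting as different by construction. The share of a difference that had to be left in a test of an explanation came to be judged with 2 standard errors. Alternatives covered scaffold and open segment length, window length, strand, copy number, motif spacing, arm, spacer and box spacing, and low-complexity sequence. Analyses used Python 3.11.15, NumPy 2.4.6, Numba 0.67.0 and Biopython 1.88, and plots used Matplotlib 3.10.9.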

Results

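The series concerned endogenous short RNAs of Mucor circinelloides, a fungus of the Mucorales, and set a wild type beside strains lacking parts of the RNA silencing machinery. The labels name 6 short RNA libraries, 1 for each of 6 genotypes. These were the wild type, the dcl1, dcl2, rdr1 and rdr2 mutants, and the double mutant of dcl1 and dcl2. Dicers (dcl) are RNase III enzymes that cut double-stranded RNA into short RNAs, and RNA-dependent RNA polymerases (rdr) copy RNA into double-stranded RNA. All strains had grown for 48 hours on YPG plates at pH 4.5, and the cultures held mycelium and spores. The reads and short RNA counts of the libraries were not analysed here, so no genotype is compared with another below, and the depth of the libraries is unknown. With 1 library per genotype, such a comparison would also have had no replicate error. The measurements below come from the deposited genomic scaffolds, the sequence to which short RNAs of this fungus can be assigned.

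The scaffolds held 36489778 bases in 23 sequences, of which 14 were at least 100000 bases long and carried 99.7% of all bases. The 10 longest scaffolds, numbered 1 to 10 in the file, ran from 6047076 down to 1341741 bases and held 91.7% of the sequence. The N50, the length at which the longer scaffolds hold 50% of the bases or more, was 4306956 bases and was reached with 4 scaffolds. Unknown bases (N) made up 0.189% of the sequence, in 85 gaps, of which 48 were exactly 100 bases long. The GC content was 42.2% over all bases. Its mean was 42.2% ± 1.10 (SD) over the 18 scaffolds of at least 10000 bases and 42.1% ± 0.25 (SD) over the 14 large ones. Among the small scaffolds, 67 stood apart at 32.7% GC, with scaffold 38 lower still, and scaffold 54 at 50.8%.

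The first question was where the scaffolds carry the enzyme families named by the mutants. The RNase III signature, a stretch of 9 residues in the catalytic domain of Dicers and other RNase III enzymes, was found at 2 loci. One was on scaffold 4, minus strand, with the signature at bases 3098607 to 3098633, inside an open segment of 468 codons at 3097902 to 3099305. The other was on scaffold 9, plus strand, at 643440 to 643466, inside an open segment of 369 codons at 642825 to 643931. Both loci read QRLEFLGDA, and their segments shared 168 of 348 aligned residues (48.3% identity). The alignment score was 811, against at most 51 in 100 alignments to shuffled sequence. Among 100 random orders of the same pattern, the highest count was 1 locus and none gave 2. No pair of complete signatures lay within 3000 bases on 1 strand, a search that did not join exons. With 1 intron allowed inside the signature, a search added after partial matches had been read, a further match fitted 9 of 9 residues on scaffold 4 and 8 of 9 on scaffold 9. With the residues already read held fixed, random downstream sequence completed as many in 18.7% and 18.9% of 1000 draws. These were the lowest shares this test could give. The labels name 2 dcl genes, and which locus is which, or whether either is one of them, was not determined.

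The Argonaute motif, from the PIWI domain of the proteins that bind short RNAs, was found at 3 loci. It read GADVTHP on scaffold 1 (minus strand, 2306989 to 2307009), GIDVSHP on scaffold 8 (plus strand, 77547 to 77567) and GADVNHP on scaffold 9 (plus strand, 522643 to 522663). Their open segments were 699, 734 and 494 codons long. The segments of scaffolds 1 and 8 shared 381 of 635 aligned residues, those of scaffolds 1 and 9 shared 300 of 494 (60.7%), and those of scaffolds 8 and 9 shared 276 of 490 (56.3%). Random orders of the pattern gave 0.26 ± 0.50 loci (SD over 100 orders), with a highest count of 2.

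The polymerase motif fixed for rdr genes, a DxDGD core followed by tryptophan, matched 1 locus. It lay on scaffold 5, plus strand, in an open segment of 875 codons at 244036 to 246660. This count alone did not stand out, because 8 of 100 random orders also gave at least 1 locus. A second motif, serine and glycine before the core, was chosen after the matches of the core had been seen. It gave 2 loci, against at most 1 in 100 random orders. These were the same locus, with SGGDLDGD at 246349 to 246372, and another on scaffold 5, plus strand, with SGGDYDGD at 2636774 to 2636797 in an open segment of 828 codons. The 2 segments shared 108 of 306 aligned residues (35.3%), with a score of 279 against at most 61 in 100 shuffles. The labels name 2 rdr genes, and these loci were not assigned to them.

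**Figure D1:**
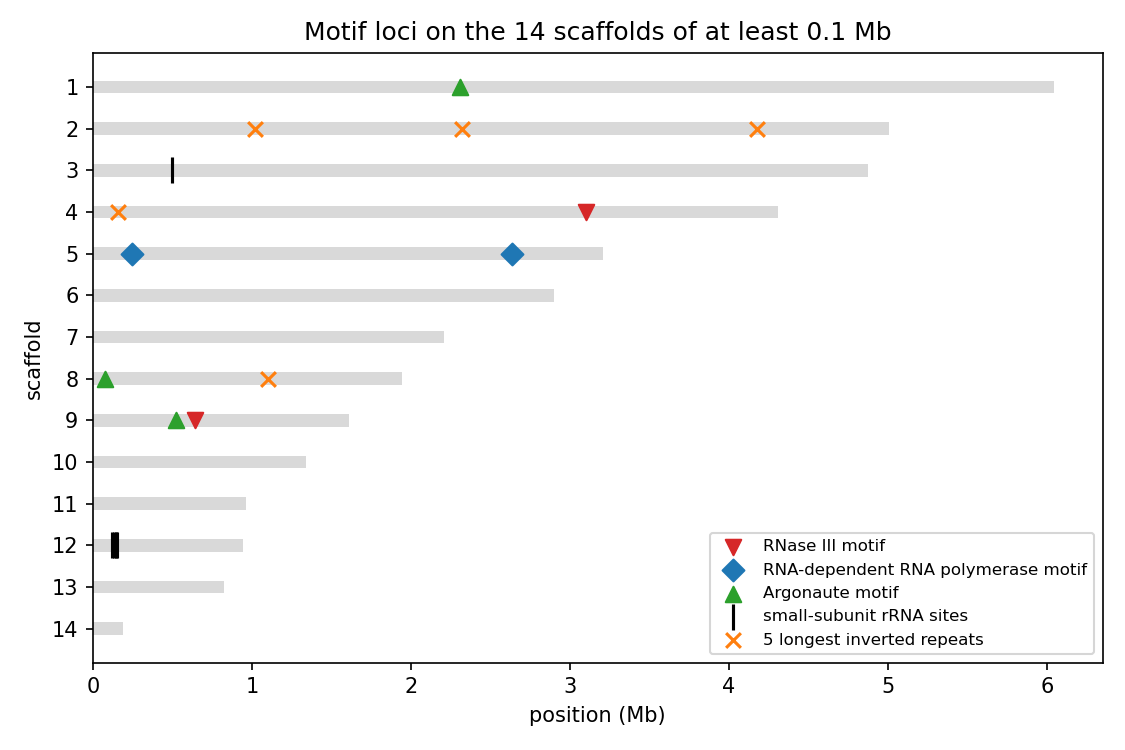
Position in Mb (x axis) of the motif loci on the 14 scaffolds of at least 0.1 Mb (grey bars, to scale), with the small-subunit rRNA sites and the start of the 5 longest inverted repeats. The RNase III motif is on scaffolds 4 and 9, the Argonaute motif on scaffolds 1, 8 and 9, and both polymerase loci are on scaffold 5.

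The second question was how much of the genome a short RNA can be assigned to without ambiguity. Of 36418663 windows of 21 nt, 84.9% occurred once over both strands, and 7.64% occurred 10 or more times. The share rose from 83.2% at 18 nt to 86.2% at 25 nt. Open segments of at least 100 codons covered 55.4% of the bases. Windows with both end bases inside them were unique in 89.7% of cases, against 78.6% with both outside. For the comparison by scaffold, each window was placed by its first base alone. Averaged over the 14 large scaffolds, the share inside exceeded that outside by 9.15 percentage points ± 8.54 (SD). It was higher in 13 of 14 (permutation p = 0.00328, two-sided, sign flips over scaffolds, adjusted p = 0.00328). Scaffold 14 was the exception at -19.0 points, and without it the excess was 11.3 ± 2.78 points. The open segments of the 7 motif loci were almost free of repeated windows. All 21-nt windows were unique in both RNase III segments, both polymerase segments and the Argonaute segment of scaffold 1, and 99.9% and 99.8% were unique in the Argonaute segments of scaffolds 8 and 9.

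**Figure D2:**
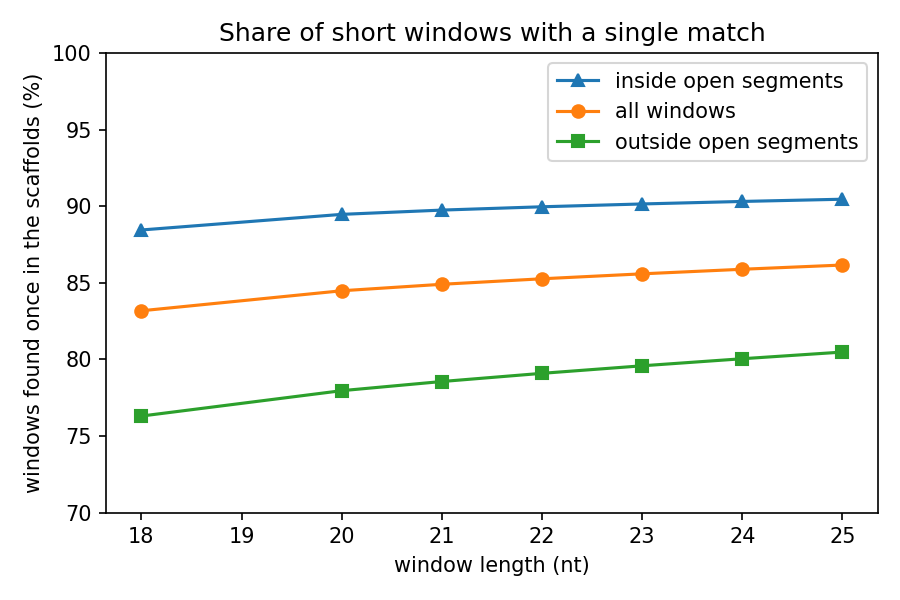
Share of windows found once in the scaffolds, counting both strands (y axis, %, not starting at 0), by window length in nt (x axis), for all windows and for windows inside and outside open segments of at least 100 codons. A window counts as inside or outside by both of its end bases. At 21 nt the values are 84.9%, 89.7% and 78.6%.

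Repeated sequence is the third point, since RNA silencing acts on repeats in many fungi. Bases covered by a 32-mer found at least 2 times made up 16.6% of the scaffolds, and those in 32-mers of at least 10 copies made up 8.82%. The most frequent 32-mer occurred 834 times. Stretches of high-copy sequence were mostly short, with a median of 60 bases, but 54 reached 1000 bases and the longest covered 4439 bases (scaffold 5, 1088589 to 1093027). Among the large scaffolds the repeated share ranged from 14.9% on scaffold 9 to 40.8% on scaffold 14. Scaffolds 17, 19, 20, 40 and 54, all shorter than 100000 bases, were repeated over 52.6%, 71.1%, 66.9%, 71.1% and 74.6% of their length. Of the remaining small scaffolds, 15 was repeated over 20.1% and 38 over 1.21%, and 67 and 72 held no repeated 32-mer. Over all bases of the 9 small scaffolds the repeated share was 35.7%.

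Repeats were poorer in G and C than single-copy sequence. Over the 14 large scaffolds the GC content was 39.1% ± 1.03 in repeats and 42.6% ± 0.592 in single-copy sequence, a difference of -3.53 percentage points ± 1.59 (SD). The difference was negative on 13 of 14 scaffolds (permutation p = 0.00031, two-sided sign flips; adjusted p = 0.000413). Scaffold 14 again went the other way, with 42.4% in repeats and 40.7% outside them. The ratio of TpA to ApT, a dinucleotide index that rises where repeat-induced point mutation has turned C into T, was 0.803 ± 0.0154 in repeats and 0.694 ± 0.0203 in single-copy sequence. It was higher in repeats on 14 of 14 scaffolds (difference 0.109 ± 0.0298, permutation p = 0.00018, adjusted p = 0.00036). Copies of the same repeat can lie on several scaffolds, so the p-values given here may be too small. Repeats lay less often in open segments, with 36.9% of their bases there against 59.2% of the other bases. With open segments left out on both sides, the GC difference was -1.93 ± 0.588 points and that of TpA over ApT was 0.049 ± 0.017. Both were smaller than over all sequence and still differed from 0, with permutation p = 0.00018 on 14 of 14 scaffolds and p = 0.00031 on 13 of 14, unadjusted. Open segments lack stop codons by definition, so leaving them out itself selects on AT content and TpA.

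**Figure D3:**
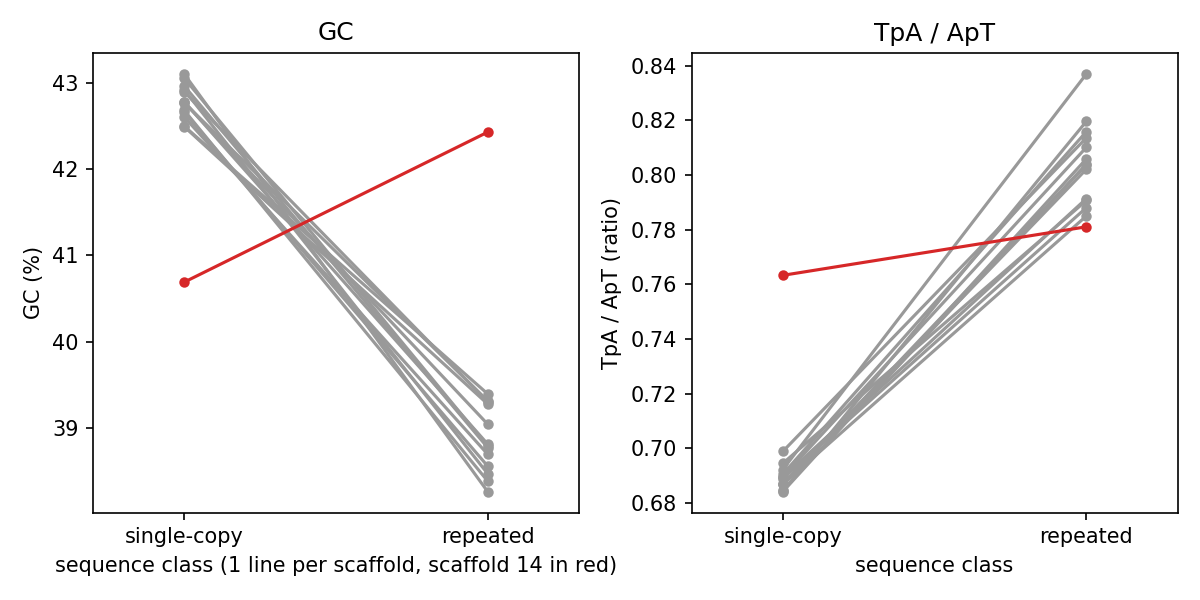
GC content in % (left) and the ratio of TpA to ApT (right) in single-copy and repeated sequence, 1 line per large scaffold, scaffold 14 in red. In repeats the mean GC content is 39.1% against 42.6%, and the mean ratio is 0.803 against 0.694; only scaffold 14 has a higher GC content in its repeats.

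Inverted repeats, whose transcripts can fold into double-stranded RNA, were counted next. Perfect arms of at least 24 bases with at most 500 bases between them were found at 142 loci, fewer than the 715 loci of direct repeats of the same arm length and spacing. The longest had arms of 2898 bases and a spacer of 201 bases (scaffold 2, 2321225 to 2327221). It was followed by arms of 2284 bases (scaffold 2, 4173590 to 4178260), 1334 bases (scaffold 2, 1016400 to 1019201), 566 bases (scaffold 8, 1102033 to 1103503) and 293 bases (scaffold 4, 156511 to 157329). None of these 5 spanned unknown bases. The arms were AT-rich, with 33.3% to 36.6% GC, and open segments of at least 100 codons touched only the longest of the 5.

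Genes of structural RNAs, a common source of fragments in short RNA libraries, were searched for last. A pair of internal promoter boxes typical of tRNA genes (an A box followed by a B box 25 to 90 bases downstream) was found at 58 loci on 12 scaffolds, against 2 loci with both boxes read backwards. These loci were almost never unique. In 52 of the 58, no 21-nt window between the box ends occurred once in the scaffolds, and 9.79% of their 2175 windows did so, against 84.9% over all windows. Telomere repeats of at least 3 TTAGGG units were found within 500 bases of 0 of 46 scaffold ends, as were runs of the scrambled unit, and the whole sequence held 1 such run.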

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

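The second polymerase motif, the parts inside and outside open segments, arms of at least 100 bases, low-complexity and distinct-window settings and the omission of scaffold 14 were chosen after seeing the data. The counts of RNase III (2) and Argonaute loci (3) held with open segments of at least 50 codons. A minimum of 200 codons could not change them, since all their segments are longer. Other largest distances of an RNase III pair tested nothing, because the 2 signatures lie on different scaffolds. The tRNA-like count was also 58 with boxes 25 to 60 bases apart. That setting could remove none, since the longest locus covered 76 bases with both boxes included. The absence of telomere repeats held with 2 units, while 5 units could add none. The polymerase count rose from 1 to 2 with the second motif. The unweighted mean GC content over scaffolds was 41.6%, because small scaffolds then weigh as much as large ones. The share of unique windows was 83.2, 84.5, 85.3, 85.6, 85.9 and 86.2% at 18, 20, 22, 23, 24 and 25 nt, 87.0% at 21 nt when only the given strand was counted, and 89.7 and 78.6% inside and outside open segments. The repeated share was 13.7% with at least 3 copies, 8.82% with at least 10 copies, 20.2% with windows of 21 bases and 13.8% with windows of 50 bases. Inverted repeats fell to 87 loci with arms of at least 30 bases, 41 with spacers of at most 200 bases and 13 with arms of at least 100 bases, by the construction of these stricter settings; direct repeats outnumbered them in each. The differences of GC content and of TpA over ApT kept their direction and stayed past the threshold under each alternative run. The planned scaling and filter of short RNA counts were not run. No reads were used, so depth sets no limit that can be given here, and how far the assembly of repeats affects the counts was not tested.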

Other observations

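The ribosomal RNA sites and the search for a signature split by an intron were chosen after the data had been seen, as were the settings that left out open segments, low-complexity sequence or repeated copies. Ribosomal RNA genes were placed with 3 conserved sites of the small-subunit rRNA gene. All 3 sites occurred in order at 5 places. On scaffold 12, plus strand, 4 copies stood in a row, beginning at 121891, 131599, 141275 and 151057, with no unknown bases between them. Their spacing was 9676 to 9782 bases. The remaining copy was on scaffold 3, plus strand, at 495961 to 497070. These are the copies present in the scaffolds, and any copies collapsed in the assembly would not be counted. Among perfect direct repeats with at most 500 bases between the copies, the longest was also on scaffold 12, with adjoining copies of 6215 bases at 38752 to 51181. Direct repeats farther apart were not searched.

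A hypothesis on the RNase III loci concerns the missing pairs. Dicers carry a pair of RNase III domains, and both tests below were run after the single signatures had been seen. As a diverged second signature without an intron, the best match within 3000 bases fitted 7 of 9 residues on scaffold 4 and 6 of 9 on scaffold 9, and as many fitted at 1.0% and 29.3% of 1000 random places, so that this explanation stays open. With 1 GT-AG intron of 40 to 150 bases allowed, 9 of 9 residues fitted on scaffold 4 (QRLEFLGDS, 3099225 to 3099316, over a gap of 65 bases) and 8 of 9 on scaffold 9 (ERLETLGDS, 642799 to 642884, over a gap of 59 bases). The partial matches QRLEFLGGI and ERLETLGGK at the same places had been read first and prompted this test, so most of the residues it counts were already known. With those residues and the GT after them held fixed, 18.7% and 18.9% of 1000 random downstream sequences completed as many. Both split matches lay upstream of the full signature, 591 and 555 bases from it. These are the lowest values the test could give, since each locus completed every residue that was not held fixed. Neither is under 5%, but a real intron could not have come under it either, so the test cannot decide. A second signature interrupted by an intron stays open as an explanation. Transcript sequence would test it.

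The lower GC content of repeats was weighed against 4 explanations. Low-complexity sequence, here 32-mers with at most 12 distinct words of 3 bases, made up 0.56% of repeated and 0.48% of single-copy windows. Sequence this simple is argued against, since it was rare and 96.5% of the difference was left without it. Leaving out so few windows could change little, and sequence of milder bias was not tested. The weight of a few high-copy families stays open. When each distinct repeated window was counted once per scaffold, 80.2% of the difference between windows was left. That share cannot decide, because a family still counts on every scaffold that holds it, and its diverged copies add distinct windows. The GC difference was -3.53 ± 1.59 points (SD) with at least 2 copies, -3.76 ± 1.84 with at least 3 and -4.22 ± 2.23 with at least 10. More coding sequence in the single-copy part stays open. Outside open segments 54.8% of the GC difference and 45.0% of the difference in TpA over ApT was left. By the 50% limit set first, the former would have counted against coding content and the latter for it, but these shares cannot measure coding content. Open segments are defined by the absence of stop codons, which are AT-rich and of which TAA and TAG contain TpA, so that leaving them out selects on the measures themselves. A change of C to T also creates stop codons. Mutation of C to T in repeats predicts a higher TpA over ApT. The difference of 0.109 met the rule set for it in advance. That rule compared repeats with single-copy sequence and set no level that the ratio in repeats had to reach. Repeated bases were defined by exact 32-mers, so copies changed by such mutation can count as single-copy sequence. The comparison may therefore leave the most altered copies out of the repeats. Such mutation cannot be told apart from coding content with these data, because no gene annotation was used. The ratio of CpA and TpG to ApC and GpT, which such mutation lowers, was compared without having been planned. It was 1.31 in repeats and 1.43 in single-copy sequence (difference -0.125 ± 0.0174, SD, lower on 14 of 14 scaffolds, permutation p = 0.00018, adjusted p = 0.00036). Outside open segments its difference was -0.0966 ± 0.0175 (SD, lower on 14 of 14 scaffolds, permutation p = 0.00018, unadjusted).

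Scaffold 14 (191544 bases) differed from the 13 other large scaffolds in its repeated share, its uniqueness at 21 nt (59.1%) and the sign of its GC difference. Unknown bases numbered 16064 on it.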
